A study of Drosophila melanogaster with 4 samples.

How the data were processed

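Tissue of wild-type Oregon-R larvae at the L3 stage was homogenised and crosslinked with formaldehyde, nuclei were lysed and sonicated, and the chromatin was immunoprecipitated with an antibody to H4K20me1, per the labels' protocols. The labels name 2 ChIP replicates and 2 inputs, and state that each input served 1 ChIP replicate. They do not say whether the replicates came from separate collections of larvae, nor the sex of the larvae, so the spread between replicates cannot be assigned to animals or to library preparation. The read aligner named in the submitters' processing notes is Bowtie 0.12.7. The coordinates are on FlyBase release 5, per the file headers, which also give the length of each sequence.

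The authors deposited 1 list of regions of significant enrichment for each ChIP replicate and 1 for the series. Regions were thus called per sample in the replicate lists; how the series-wide list combined the replicates, the region caller, its settings and its threshold are not given in the sources used here. No signal or read count was used here for the ChIP or input samples, so the input enters only through the authors' calls. Each region carries a start, an end and the authors' score, whose definition is not given per the file headers. Its scale was settled from the values. After subtracting a score that recurs in the list, 2 raised to the score was a ratio of whole numbers with a denominator of at most 2000 (within a relative tolerance of 1e-11) for 95.1% of the 6478 regions of replicate 1, 96.4% of the 5209 of replicate 2 and 82.6% of the 5318 of the series-wide list. With a natural or base-10 logarithm this held for at most 1.13%. The deposited score is therefore treated as the log2 of a scaled ratio. It is used to describe and rank regions within a list and, between the replicates, in rank correlations; the offset of each list is unknown, so score sizes were not tested between lists. Read depth is unknown, and no limit that needs it is given.

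Rows marked as enriched were kept; 1 row of replicate 2 is marked as depleted and was left out of the comparisons. One region of replicate 1 on 3L ran 685 bp past the sequence end in the header and was clipped there. Coordinates are 1-based. Uextra held 0 regions in the 3 lists and was left out of the assembled total. The gene table given with the data is of another release, so the planned comparisons of genomic features, genes and gene lists were not run, and no gene is named. Under the rule fixed for that case, the regions named are the 10 longest and the 10 highest-scored of the series-wide list that overlap both replicates, and the longest on each sequence. The comparisons, this rule and most of the other settings tried were fixed before the data were examined. The exceptions are the header lengths of the sequences and the 5 major arms only. Others are X without the 2 Mb next to the centromere and X with regions within 5 kb joined. The X test was fixed within each replicate, and its use on the bases enriched in both replicates was not named beforehand.

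Overlaps needed at least 1 bp. The Jaccard index is the number of bases enriched in both replicates divided by the number enriched in either. It was compared with 1000 circular shifts of the replicate 2 regions within each sequence, which keep region lengths and spacing. The same number of shifts gave the chance share of regions found in the other replicate. Shares of regions carry exact Clopper-Pearson 95% intervals, which cover counting error only. Coverage is the number of enriched bases divided by the sequence length in the header. The length fixed beforehand was the span from the first to the last series-wide region; the header length was used instead once the headers were seen to give it. XHet and YHet hold a single series-wide region each, which leaves no usable span there. With the span, coverage was 20.8% on X and 22.8 to 28.5% on the autosomal arms (means of the replicates), and 49.1% and 12.7% on chromosome 4 in replicates 1 and 2. X was compared with 2L, 2R, 3L and 3R over full windows of 1 Mb with a two-sided permutation test (100000 resamples), and by 10000 circular shifts of the joined arms in bins of 10 kb. These were 4 tests in 1 family (2 replicates, both together, and the series-wide list), with Benjamini-Hochberg adjustment over the 4 for each kind of test. Because there is 1 condition, no test between groups was made.

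The overlap test and the X test were tested on simulated lists of 6028 regions on the major arms, with lengths drawn from replicate 1, in 20 simulations each, with 99 shifts for each overlap test. The overlap test passed 0.05 in 20 of 20 simulations with 50% of the regions copied and in 1 of 20 with unrelated lists. The X test over windows passed in 20 of 20 simulations with 40% of the regions dropped from X and in 3 of 20 with none dropped. The simulated lists kept the number of regions on each arm, 48.3 per Mb on X and 51.2 on the autosomal arms. Regions were placed at random without the clustering of the real lists, and dropping 40% made a larger deficit than the observed one. These rates are therefore not error rates or power for the real lists. Alternatives were the upper-scoring 50% of each list, a length minimum of 1 kb, joining of regions within 1 kb, stricter overlaps, windows of 250 kb and 2 Mb, each replicate alone and the series-wide list. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.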

Results

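Monomethylation of histone H4 at lysine 20 (H4K20me1) is a chromatin mark deposited by the methyltransferase PR-Set7. Its distribution was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in nuclei of wild-type Oregon-R Drosophila melanogaster at the third larval instar (L3), with one antibody lot. The series holds 2 ChIP replicates and 2 input samples, 1 input for each ChIP. The measurements used here are 3 lists of enriched regions on the FlyBase release 5 genome, 1 per ChIP replicate and 1 for the series as a whole. There is a single condition, so the comparisons are between the replicates, between chromosome arms and between regions. Read depth is unknown, because the lists give no counts. A gene annotation of release 5 was not used here, so regions are named by position and not by gene.

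H4K20me1 formed many short regions and a small number of very long ones, and covered about the same amount of the genome in both replicates. Replicate 1 had 6478 enriched regions over 31.8 Mb, which is 22.7% of the 140 Mb of assembled sequence, and replicate 2 had 5209 regions over 28.2 Mb, which is 20.2%. The median region was 2505 bp long in replicate 1 and 3076 bp in replicate 2. The 700 regions of 10 kb or more in replicate 1 held 43.9% of its enriched bases, and the 654 such regions in replicate 2 held 44.0%. Regions of 50 kb or more numbered 24 in replicate 1 and 17 in replicate 2. On the 5 major arms 28.4% of the gaps between neighbouring regions in replicate 1 and 28.8% of those in replicate 2 were under 1 kb. The authors' score of a region, a log2 value, had a median of 0.71 in replicate 1 and 0.71 in replicate 2; the offset of each list is unknown, so these are not folds and their sizes are not compared between lists. The longer regions had the higher scores, with a Spearman's rho across regions of 0.52 in replicate 1 and 0.81 in replicate 2. Regions within a list are not independent replicates, and whether the score is a mean, a maximum or a bound over the region is unknown; a maximum or a bound can rise with length by construction.

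The first comparison asked how far the replicates marked the same places. Of the bases enriched in replicate 2, 81.4% were also enriched in replicate 1, and 72.2% of the replicate 1 bases were enriched in replicate 2. The 22.9 Mb enriched in both made up 62.0% of the 37.0 Mb enriched in either (Jaccard index). Circular shifts of the replicate 2 regions along each sequence gave a median Jaccard index of 13.7% and at most 20.2% in 1000 shifts (one-sided permutation p = 0.001, the smallest these shifts can give). Counted as regions that share at least 1 bp, 4300 of the 6478 replicate 1 regions (66.4%, exact Clopper-Pearson 95% interval 65.2 to 67.5%) were found in replicate 2. In the other direction 4320 of 5209 were found (82.9%, 81.9 to 83.9%). The shifts gave medians of 32.4% and 39.1% for these shares. Such intervals cover counting error over regions only. When each region had to cover at least 50% of its partner and be covered by it over at least 50%, 2385 regions matched.

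Long regions were found in both replicates and short ones often were not. All 221 replicate 1 regions of 20 kb or more were found in replicate 2 (lower 95% limit 98.3%), as were all 179 such replicate 2 regions in replicate 1 (lower limit 98.0%). Between 5 and 10 kb the shares were 94.7% and 98.5%. Under 2 kb they were 38.6% of 2416 replicate 1 regions (36.6 to 40.6%) and 61.1% of 1307 replicate 2 regions (58.4 to 63.7%). Long regions also meet another region more often by chance. The shifts gave medians of 61.1% and 68.7% at 20 kb or more, and of 26.3% and 31.8% under 2 kb, and the observed shares exceeded the highest of the 1000 shifts in every length class of both lists. Over the 4300 replicate 1 regions paired with the replicate 2 region of largest overlap, Spearman's rho across regions was 0.53 for the score and 0.50 for the length. For the 2385 pairs with reciprocal overlap of at least 50% it was 0.75 for the score. The value for the length, 0.92, is largely set by that condition, which bounds the ratio of the lengths. The score rose with length within each list, so the condition can also raise the value for the score.

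**Figure D1:**
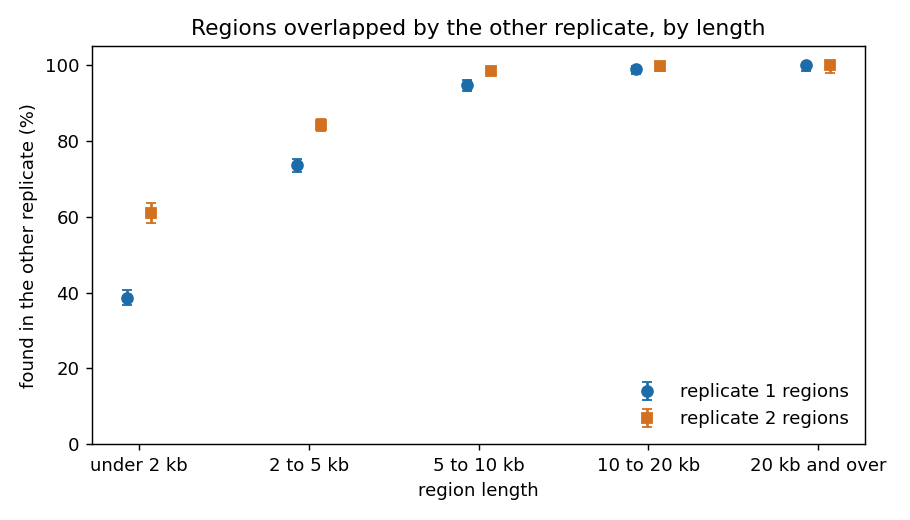
Share of enriched regions overlapped by at least 1 bp of the other replicate (vertical axis, percent), by region length (horizontal axis). Points are the 2 lists and bars are exact 95% intervals; the share was 38.6% and 61.1% under 2 kb and 100% in both lists at 20 kb and over.

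The series-wide list had 5318 regions over 33.4 Mb. Of its bases, 68.5% were enriched in both replicates, 15.0% in replicate 1 alone, 12.0% in replicate 2 alone and 4.43% in neither. It contained 99.8% of the bases enriched in both replicates, 56.9% of those enriched in replicate 1 alone and 76.6% of those enriched in replicate 2 alone, so it was neither the union nor the intersection of the replicate lists. Of its regions, 3271 overlapped both replicates and had a median length of 5491 bp and a median score of 0.69. The 439 that overlapped neither had a median length of 1211 bp and a median score of 0.37.

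The second comparison was between chromosome arms. Among the 5 major arms, 2R was the most covered, with 28.5% ± 0.95 of its bases enriched (mean ± SD, n = 2). The share was 25.5% ± 0.39 on 3R, 24.8% ± 2.42 on 3L, 22.8% ± 2.24 on 2L and 20.8% ± 1.41 on X. X was the lowest of these arms in each replicate, at 21.8% in replicate 1 against 24.4 to 29.2% on the autosomal arms, and at 19.8% in replicate 2 against 21.2 to 27.8%. The difference between the means of X and 2L was smaller than the spread between the 2L replicates. That spread includes the higher coverage of replicate 1 on every major arm. Within each replicate X lay below 2L, at 21.8% against 24.4% and at 19.8% against 21.2%.

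The X chromosome had about as many regions as the autosomal arms but fewer long ones. Its density was 48.3 regions per Mb in replicate 1 and 43.8 in replicate 2, against 51.2 and 42.8 on the autosomal arms. Regions of 10 kb or more numbered 4.28 and 3.88 per Mb on X, against 5.99 and 5.84 on the autosomal arms. The median score on X was 0.73 in replicate 1 and 0.74 in replicate 2, against 0.67 and 0.70 on the autosomal arms. The difference in covered share was tested over windows of 1 Mb, 22 on X and 95 on the autosomal arms. For the bases enriched in both replicates the mean window was 15.4% covered on X and 20.0% on the autosomal arms, a difference of -4.66 percentage points (two-sided permutation test over windows, p = 0.012, or 0.046 after Benjamini-Hochberg adjustment over the 4 tests made). It was -4.38 points in replicate 1 alone (permutation p = 0.029, adjusted 0.059) and -4.24 points in replicate 2 alone (permutation p = 0.046, adjusted 0.062), so neither replicate passed 0.05 alone after adjustment. The test fixed beforehand was the one within each replicate, not the one on shared bases. The bases enriched in both also fall where the replicates agree less. Their Jaccard index was 57.2% on X and 65.1% on the autosomal arms, so the difference for shared bases does not measure coverage alone. Windows are not biological replicates, and neighbouring windows resemble one another. When the arms were instead shifted as blocks, which keeps neighbours together, the difference was not significant (permutation p = 0.087 for both replicates, 0.060 for replicate 1 and 0.16 for replicate 2, all at least 0.17 after adjustment). In the series-wide list it was -3.38 points and passed neither test (permutation p = 0.13 over windows and 0.19 by block shifts). X makes up 22.4 of the 119 Mb shifted as blocks, so few of these shifts are independent. The block test was not tried on simulated lists and its power is unknown.

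**Figure D2:**
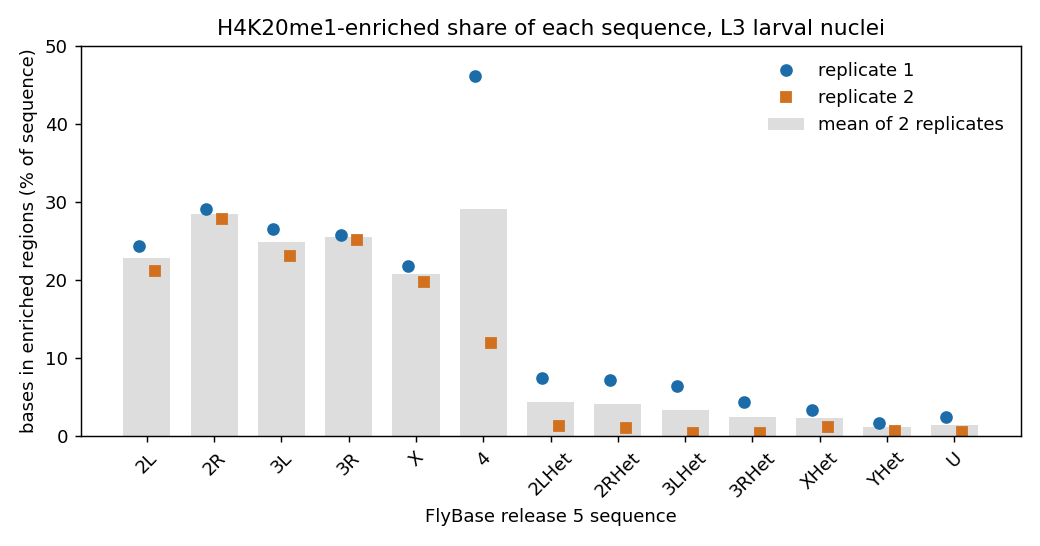
Share of the bases of each release 5 sequence that lie in H4K20me1-enriched regions (vertical axis, percent; bars, mean of 2 replicates; points, the replicates). The replicates lie close together on the 5 major arms, where X is lowest at 20.8% on average, and far apart on chromosome 4, at 46.1% and 12.0%.

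Chromosome 4 and the heterochromatic sequences differed between the replicates more than any major arm. Chromosome 4, a small chromosome largely made of heterochromatin, was enriched over 46.1% of its length in replicate 1 and 12.0% in replicate 2, with 132 and 44 regions. The 7 heterochromatic and unplaced sequences (2LHet, 2RHet, 3LHet, 3RHet, XHet, YHet and U) were enriched over 4.12% of their 19.3 Mb in replicate 1 and 0.58% in replicate 2, with 318 and 45 regions. The ratio of replicate 1 to replicate 2 was 3.85 on chromosome 4 and 7.15 on these sequences, against 1.09 on the 5 major arms. Both replicates covered less of the heterochromatic sequences than of any major arm. These shares are of the full length in the headers, while the series-wide regions spanned 14.6 of the 19.3 Mb. How much of these sequences could hold placed reads is unknown, so the low share does not show that the mark is depleted there. On chromosome 4 all 44 replicate 2 regions lay on replicate 1 regions (lower 95% limit 92.0%), while shifts gave a median of 65.9% and up to 100%. Of the 132 replicate 1 regions there, 37 were found in replicate 2 (28.0%, 20.6 to 36.5%), which was within the range of the shifts (median 22.7%, at most 32.6%). With only 44 replicate 2 regions there, this count had little room to exceed the shifts, so it cannot show whether the replicates agree beyond chance. By bases, 11.8% of chromosome 4 was enriched in both replicates, against 12.0% in replicate 2. On the heterochromatic sequences 32 of 318 replicate 1 regions (10.1%, 7.0 to 13.9%) were found in replicate 2, above the shifts (at most 4.09%), and 39 of the 45 replicate 2 regions (86.7%, 73.2 to 94.9%) were found in replicate 1. With 1 library on each side, these differences compare 2 libraries.

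Along the major arms the covered share of a 1 Mb window ranged from 4.58% to 48.6% (mean of the replicates), with a median of 24.5% over 117 windows. The replicates ordered the windows alike (Spearman's rho across windows 0.87), and the median SD of a window was 2.19 points. The most covered windows were 3R from 5 to 6 Mb, at 48.6% ± 2.55 (SD, n = 2), 2R from 6 to 7 Mb, at 42.1% ± 0.43, and 3L from 3 to 4 Mb, at 41.9% ± 3.08. The least covered were 3L from 23 to 24 Mb, next to the centromere, at 4.58% ± 5.05, and 2L from 15 to 16 Mb, in the body of the arm, at 5.36% ± 1.05. The first 1 Mb of 2R, at its centromere end, had 16.1% in replicate 1 and 2.26% in replicate 2. The replicates differed most from 1 to 2 Mb on 2R, at 26.6% and 10.2%, and from 14 to 15 Mb on 3L, in the body of the arm, at 40.7% and 25.8%; these windows were picked for that difference.

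**Figure D3:**
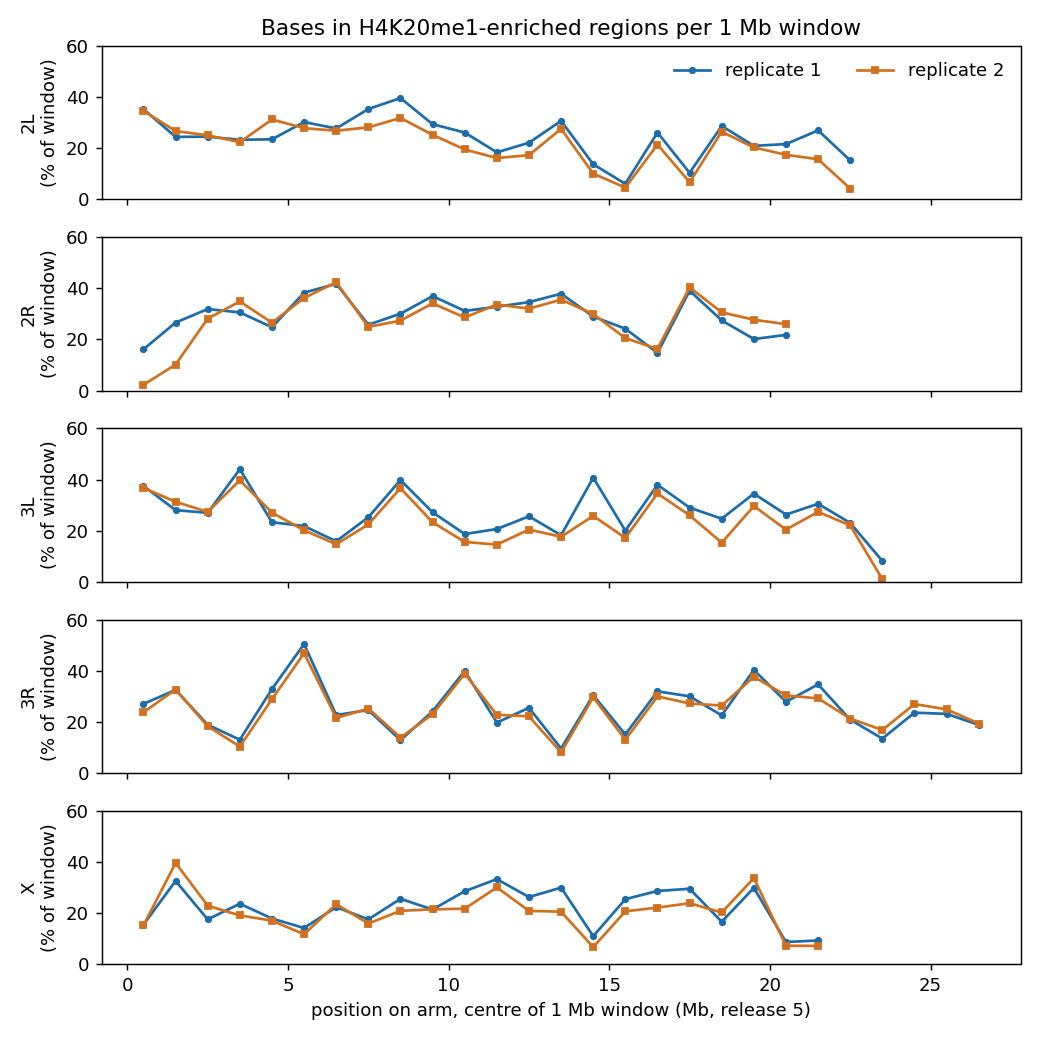
Share of each full 1 Mb window in H4K20me1-enriched regions (vertical axis, percent) along the 5 major arms (horizontal axis, Mb), for replicate 1 and replicate 2. The 2 lines run together over most of each arm, peak on 3R between 5 and 6 Mb at 48.6% on average, and part at the centromere ends of 2L, 2R and 3L and on 3L between 14 and 15 Mb (40.7% and 25.8%).

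The longest domains lay on every major arm and were enriched in both replicates over most of their length. The 10 longest regions of the series-wide list that overlapped both replicates were 82.1 to 114 kb long, and between 88.2% and 99.1% of each was enriched in both. They were 4 regions on 3R, 3 on 2R and 1 each on 2L, 3L and X. The longest, on 3L from 22287092 to 22401048, spanned 114.0 kb with a score of 0.92. It was a single region in replicate 2 and was split into 9 regions in replicate 1, which covered 93.4% of it. On 3R, the domain from 10217008 to 10307772 (90.8 kb, score 1.30) was enriched over 96.7% of its length in replicate 1 and 99.5% in replicate 2, and the domain from 4893860 to 4984342 (90.5 kb, score 1.14) over 98.8% and 97.3%. The longest domain on 2R ran from 17278346 to 17368736 (90.4 kb, score 1.12), and that on 2L from 7891792 to 7977608 (85.8 kb, score 1.24), where each replicate had a single region. The longest on X ran from 19247182 to 19332174 (85.0 kb, score 1.18), of which 99.1% was enriched in both replicates. The longest on chromosome 4, from 134436 to 149900, was 15.5 kb long, and replicate 2 covered 69.2% of it.

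**Figure D4:**
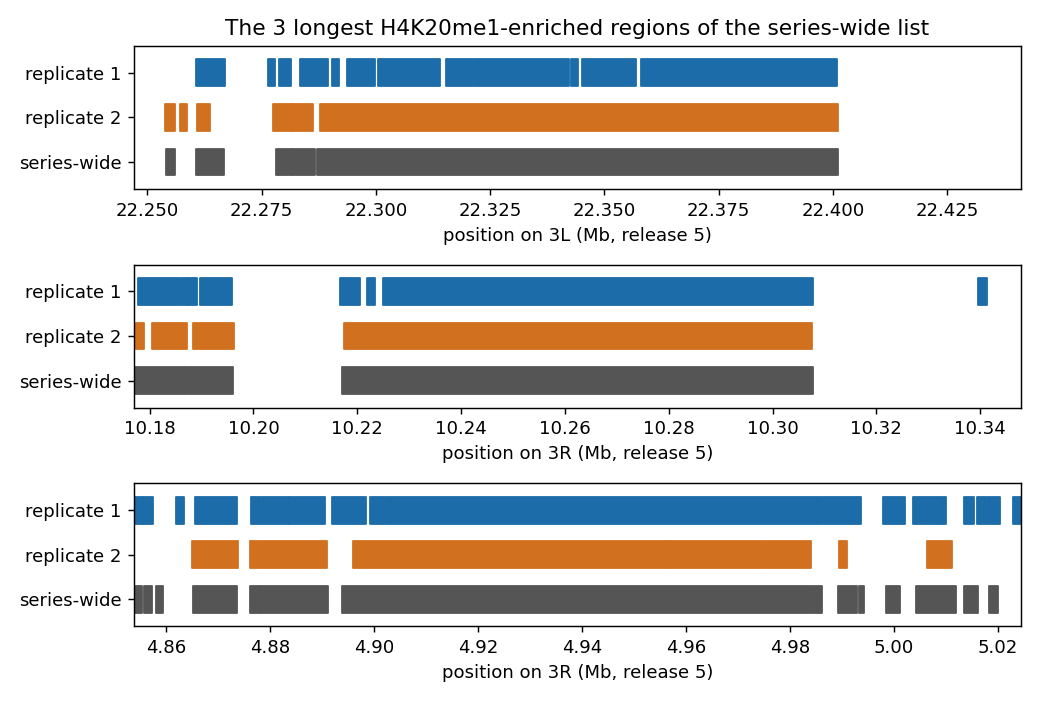
Enriched regions of the 3 lists (rows) around the 3 longest regions of the series-wide list, drawn to scale by position (horizontal axis, Mb). The 114 kb domain on 3L is one block in replicate 2 and 9 blocks in replicate 1, while the domains of 90.8 and 90.5 kb on 3R are each covered over at least 96.7% of their length in each replicate.

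The highest-scored regions of the series-wide list that overlapped both replicates were shorter than these domains. Without the condition on overlap, 6 of the 10 highest-scored regions of that list lay on heterochromatic or unplaced sequences, and the median length of the 10 was 1011 bp. The 10 highest scores with it ran from 1.96 to 2.21, and the regions were 6.0 to 48.4 kb long. There were 4 on 3R, 2 each on 2L and 2R, and 1 each on 3L and X. The first was on 3L from 16131024 to 16158118 (27.1 kb), with a score of 2.21. The next were on 3R from 4636534 to 4647058 (10.5 kb, score 2.18) and from 5166804 to 5190432 (23.6 kb, score 2.16). The latter lies in the most covered 1 Mb window of the major arms. On X the highest was from 1528530 to 1563164 (34.6 kb, score 2.10), and on 2L from 154890 to 203308 (48.4 kb, score 2.07). No region was shared by this group and the 10 longest.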

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

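Of the settings here, the 5 major arms only, X without the 2 Mb next to the centromere, X with regions within 5 kb joined and the header lengths of the arms were chosen after seeing the data. The Jaccard index stayed above chance in all 4 settings tried, at 56.4% for the upper-scoring 50% of each list, 62.0% for regions of at least 1 kb, 63.2% with regions within 1 kb joined and 63.8% on the 5 major arms only. The length minimum removed 1 region of replicate 1, so it tests nothing. Counts moved by over 1.5 times with the upper-scoring 50% and with reciprocal overlap, and by less with at least 50% of the region covered (3583 replicate 1 and 3713 replicate 2 regions). With the upper-scoring 50%, 1756 replicate 1 regions and 1930 replicate 2 regions were found in the other list and 1614 series-wide regions overlapped both replicates, which follows from the shorter lists. With reciprocal overlap of at least 50%, 2385 regions matched in each direction. The rank correlation of scores rose to 0.75 with reciprocal overlap, which selects pairs of like length and can raise it, since the score rose with length within each list. The smaller covered share of X kept its direction in every alternative run. The difference ran from -4.99 points with regions within 5 kb joined to -3.11 points with the upper-scoring 50%. Each replicate alone gave -4.24 and -4.38 points. Unadjusted, the difference kept its side of 0.05 in all but the series-wide list (permutation p from 0.003 to 0.046 over windows). These settings reuse the same lists, and neither replicate alone passed 0.05 after adjustment. The lowest p came from windows of 250 kb, where neighbouring windows are treated as independent. The reported value, for the bases enriched in both replicates, was not a comparison named beforehand. In the series-wide list the difference was -3.38 points and no longer significant (p = 0.13, permutation over windows), and the cause was not tested. Among the settings with block shifts, these passed 0.05 for the upper-scoring 50% alone (p = 0.040, permutation). X stayed the lowest major arm in 8 of 8 settings, the reported one included. Of the recomputed arm shares, 20 moved by less than the spread between replicates and 22 by more. For single lists the latter follows from comparing them with the bases shared by both. No paired analysis was possible between ChIP and input because the input samples have no region lists and there is a single ChIP group. The arms were measured in both replicates. Over the joined arms, X minus the autosomal arms was -4.58 points in replicate 1 and -4.49 points in replicate 2. These differences were not tested as pairs. Other settings for genomic features, genes and gene lists were not run, as no annotation of the build was used. Depth is unknown, so a region missing from 1 replicate cannot be told from one below its detection limit.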

Other observations

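The tests of a looser threshold, of gaps and broken domains on X, of the centromere ends and all those at matched lengths were chosen after the result was seen; the unmatched tests on shared exact scores under 5 kb and under 2 kb on the major arms were set before it.

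The highest scores of replicate 1 lay mostly outside the major arms. Of its 10 highest-scored regions, 8 were on heterochromatic or unplaced sequences, with a median length of 1669 bp over the 10. In replicate 2 it was 2 of 10, with a median length of 9262 bp, and in the series-wide list 6 of 10, with a median length of 1011 bp. The 10 longest regions of the series-wide list that overlapped both replicates were all on major arms. Next to the centromere, over 2 Mb of each arm, replicate 1 covered 2.16 times as much as replicate 2 on 2L, 3.43 times on 2R, 2.86 times on 3L, 1.51 times on X and 1.06 times on 3R, against 1.00 to 1.13 times over the rest of these arms.

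The larger covered share of chromosome 4 and of the heterochromatic sequences in replicate 1 was weighed against 2 technical explanations; both libraries carry the same labels, so no biological explanation was tested, and a difference between larval collections stays open. Whether a looser threshold in replicate 1 was the cause could not be decided, since the threshold is not given and length was used in its place. A limit on the score was not tried. Replicate 1 regions scored high on these sequences, so it was expected to remove few of them. Their median score was 1.21 on the heterochromatic sequences and 1.05 on chromosome 4, against 0.69 on the major arms. Limited to its 5209 longest regions, replicate 1 still covered 5.81 times as much of the heterochromatic sequences as replicate 2. The ratio was 3.63 on chromosome 4 and 1.03 on the major arms. The limit removed 33.3% of its heterochromatic and 18.9% of its chromosome 4 regions, all of them under 2 kb. Regions under 2 kb held only 38.6% and 14.0% of its enriched bases there. Removing them could therefore not bring these ratios near that of the major arms. Scores resting on few counts were weighed within replicate 1 only, by exact scores that another region of the list also had. No counts were available, so taking a shared score as a sign of few counts is an assumption. Replicate 2 was not examined in this way, so the shares cannot tell why the replicates differ. Regions of 1 library are also not independent replicates, and shared scores come in groups, which the tests below do not allow for. Under 2 kb, 66.3% of 196 heterochromatic and 67.3% of 55 chromosome 4 regions had such a score. Major-arm regions of the same lengths gave 43.3% and 42.6% (permutation within length bins of 250 bp, two-sided p = 2.0e-05, the smallest it can give, and 0.00038). Under 5 kb the shares were 51.4% and 43.3%, against 35.7% and 31.6% (permutation p = 2.0e-05 and 0.017). Fisher's exact test without matching gave p = 8.0e-14 and 0.005 under 5 kb. From 2 to 5 kb the shares were 21.4% and 11.9%, against 20.5% and 17.3% (permutation p = 0.93 and 0.48), which decides nothing. Regions under 2 kb held 38.6% of the enriched bases of replicate 1 on the heterochromatic sequences and 14.0% on chromosome 4, and the explanation could not be tested for the 19 regions of 10 kb or more on chromosome 4 (21.9% of it, against 2.45% in replicate 2), where 0% shared a score but only 0.74% of such major-arm regions did.

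For the smaller covered share of X, the centromere ends are argued against as the whole cause. Without the 2 Mb next to the centromere of each arm the difference was -4.38 points, against -4.66 points with them. With regions within 5 kb joined it was -4.99 points, so joining did not bring X closer in points. Joining also raises coverage on the autosomal arms, and the joined shares are not given here, so small gaps are not excluded. Whether the lower number of long regions on X reflects long domains broken into pieces by the calling could not be decided. X had 0.71 times (replicate 1) and 0.66 times (replicate 2) as many regions of 10 kb or more per Mb as the autosomal arms. With regions within 5 kb joined it had 0.88 and 0.92 times as many, on either side of the bound of 0.9 set for this test. The median gap on the major arms was 3109 bp in replicate 1 and 2987 bp in replicate 2. Joining thus merged most neighbouring regions there, and gave 9.19 and 8.28 such domains per Mb on the autosomal arms. Such merging can bring X and the autosomal arms closer even if no domain was broken. Chance arrangement along the arms also stays open, since block shifts gave p = 0.087 (permutation), as does the dose of X in male larvae, which was not tested since the labels give no sex.

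Short regions seen in replicate 1 alone did not have the lower scores. On the major arms, the 1238 replicate 1 regions under 2 kb that were missing from replicate 2 had a median score of 0.63, against 0.45 for the 927 that were found. In replicate 2 the medians were 0.51 and 0.49. A candidate explanation is that scores resting on few counts must be high to be called: 50.7% of the missing regions had an exact score that another region also had, against 32.4% of those found (Fisher's exact test, two-sided p = 9.5e-18), or 32.9% at the same lengths (permutation p = 2.0e-05). Among these replicate 1 regions 42.8% were found, while the shifts gave a median of 28.9%. Many of the found regions may thus overlap by chance, and regions of 1 library are not independent replicates. That a shared score marks few counts is an assumption here too. No biological explanation was tested.

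The 1 region marked as depleted, in replicate 2 on 2R from 11566440 to 11568041 (score -0.01), lay wholly inside a replicate 1 region from 11566111 to 11568147 with a score of 0.56, and wholly inside the series-wide list, at a score of 0.32.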
